A study of Nothobranchius furzeri with 10 samples.

How the data were processed

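RNA sequencing was used to measure gene expression in the skin of male turquoise killifish (Nothobranchius furzeri) aged 10 weeks. All samples were from a line carrying the transgene Tg(mylz2:egfp,tfam). Total RNA was made into libraries with the Illumina TruSeq RNA v2 kit, per the labels' protocols. The 10 libraries fell into 2 groups of 5: skin taken with swim-tunnel exercise and skin taken without exercise. The labels give neither the length nor the intensity of the exercise. They also do not say whether each library came from a separate animal, so the p-values measure the spread between these samples, which may be technical in part. Replicate numbers were given in the order of the samples, which is also that of the running numbers in their titles. The labels state no pairing across groups, so none was used, and a shared order of the samples cannot be ruled out from them.

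The authors deposited a table of counts per gene. Per the submitters' processing notes, bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 were used. The genome build, the annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Reads shared between near-identical genes, overlapping genes or a gene and its antisense partner can therefore not be assigned with certainty. The counts were used as deposited and ran from 22991447 to 44051324 per library.

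The deposited RPKM table was made by the authors from the same counts, but its values were not divided by the total of their own library. Down each column the 10 library totals were used in turn. With these totals 100% of 148119 values of at least 1 RPKM matched within 0.1%, against 12.04% with each library's own total. Own totals therefore entered 10% of the values, and the others were off by a factor of 0.522 to 1.92. Gene lengths for both shares were recovered with the totals taken in turn, so the 12.04% is low in part through that choice. The 100% rests on 1 length per gene that holds across its values. The deposited RPKM values were used only as an alternative input and to recover gene lengths. Of the recovered lengths, 52.7% were divisible by 3, so some gene models may hold no untranslated regions, and "gene length" is the length of the model used by the authors.

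The main comparison was made with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, at a minimum count of 10 and a minimum total of 15, and libraries were scaled with TMM factors. A robust quasi-likelihood fit was followed by the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method. A gene was counted as changed at an adjusted p below 0.05. Standard errors were computed as the absolute log2 fold change divided by the square root of F. CPM values were scaled with the TMM factors, and log2 CPM used a prior count of 2. The median biological coefficient of variation was 21.5%. In data simulated for this comparison from the 18632 tested genes, with 50 genes changed at each size, 22% were recovered at 1.5-fold, 60% at 2-fold, 90% at 3-fold and 98% at 4-fold, and 8 of 143 calls were false (5.59%). Genes were simulated independently, with no other difference shared between libraries, so these shares need not hold for the real data. Library measures were compared with exact two-sided permutation tests. Counts of pairs of libraries were tested for duplicates by chi-square, whose lowest value per degree of freedom was 25.6, so no pair was treated as 1 library.

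The rule for the genes to be named was fixed before the data were examined. It took the 10 with the largest change in each direction among genes with an adjusted p below 0.05, a gene symbol, a mean log2 CPM of at least 1 and no overlap between the groups, with changed members of fixed gene lists and tfam added. The count table holds identifiers without names, and 0 of its 26739 identifiers matched the reference table of 38438 genes (assembly NfurGRZ-RIMD1). The 297 higher and 190 lower genes that met every other condition of the first part thus had no symbol. After this was seen, the condition on the symbol was dropped and the first 2 identifiers in each direction were taken. The 32 gene lists fixed beforehand, their tests and scores, a covariate from muscle genes and the level of tfam were not analysed here for the same reason.

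Alternatives fixed before the data were examined were other scaling factors, filters and thresholds, DESeq2 1.42.0 with its own filtering, limma 3.58.1 with voom quality weights or on log2 deposited RPKM plus 0.1 or 1, 1 surrogate variable from sva 3.50.0, and the removal of each library in turn. A further 6 were added after the data had been seen: RPKM recomputed with each library's own total, removal of each library's trend on gene length, thinning of all libraries to 22991447 counts, a comparison of 4 against 4 libraries, and 2 models with the running number of the sample titles as a term. In all, 27 refits were made beside the main one. Other splits of the libraries into 5 and 5 were tested with 100 of the 126 possible splits. Figures were drawn with matplotlib 3.10.9.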

Results

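Gene expression was measured in killifish skin with and without swim-tunnel exercise. In a swim tunnel a fish swims against a current of water. The transgene carried by all samples joins the promoter of a muscle myosin light chain gene (mylz2) to a green fluorescent protein and to tfam, which encodes a factor that packages and transcribes mitochondrial DNA. Each group held 5 libraries. Replicates 1 to 5 with exercise held 33637143, 22991447, 36851296, 33649176 and 33779115 counts, and replicates 1 to 5 without exercise held 37816124, 44051324, 31202716, 29236646 and 28142026. The difference between the group means of these totals was smaller than the spread between libraries (n = 5 each, exact permutation test, two-sided, p = 0.64). Of 26739 genes in the table, 4021 had no count in any library and 18632 had enough counts to be tested.

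Pearson's r of log2 CPM across genes, which are not independent replicates, lay between 0.937 and 0.985 for the 20 pairs of the same group and between 0.93 and 0.977 for the 25 pairs of different groups. The lowest value in each set belonged to exercise-group replicate 1, which also scored -85.2 on the first principal component, where the other 9 libraries scored -21.6 to 33.2. The first 3 principal components, with 27.9%, 20.2% and 13.8% of the variance, did not separate the groups (exact permutation tests, two-sided, p = 0.2, 0.49 and 0.51). On the 4th component, with 11.8% of the variance, all 5 libraries with exercise scored above all 5 without. Its scores were 17.7 ± 15.9 with exercise and -17.7 ± 10.4 without (SD, n = 5, exact permutation p = 0.0079, the smallest this design can give). The p-value adjusted over the 8 library measures tested was 0.063.

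**Figure D1:**
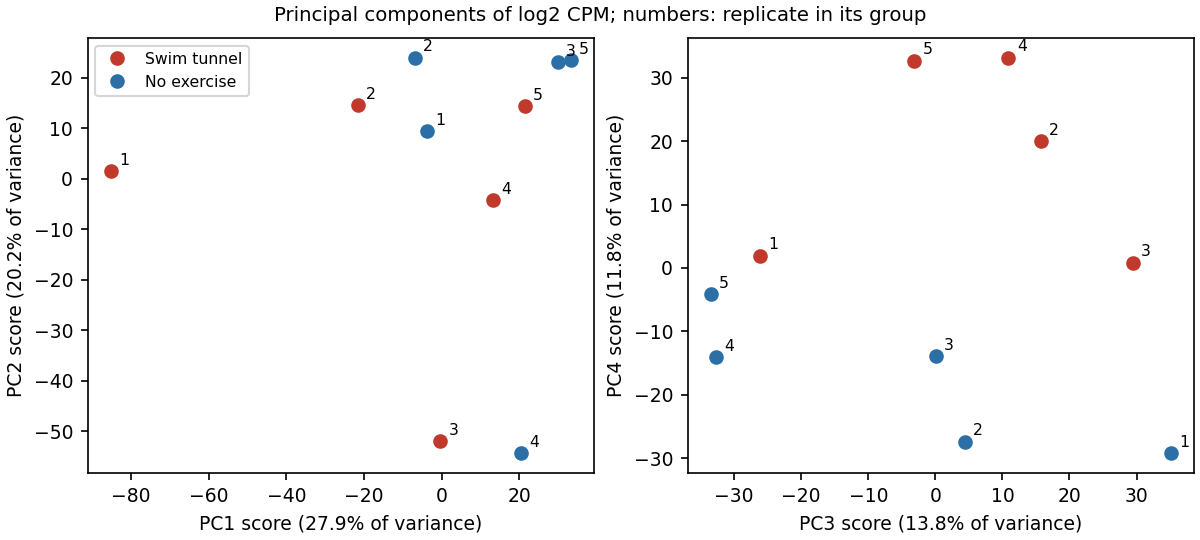
Scores of the 10 libraries on principal components 1 and 2 (left) and 3 and 4 (right) of log2 CPM, in red with exercise and in blue without; each point is 1 library, numbered by its replicate. The groups overlap on components 1 to 3 and lie apart on component 4, which holds 11.8% of the variance.

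The comparison of the groups asked which genes of the skin differ in expression with swim-tunnel exercise. Of the 18632 tested genes, 534 (2.87%) differed, of which 324 were higher and 210 lower with exercise (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The genes that were higher took 1.68 ± 0.122% of all counts with exercise and 1.08 ± 0.0743% without. The genes that were lower took 0.621 ± 0.0496% with exercise and 0.881 ± 0.0565% without (SD, n = 5); both lists were chosen for this difference. Most changes were modest, with a median log2 fold change of 0.58 among the higher and -0.58 among the lower genes and a median standard error of 0.11. Among the higher genes 40 changed by at least 2-fold, 120 by 1.5 to 2-fold and 164 by less than 1.5-fold. Among the lower genes these numbers were 22, 80 and 108. The log2 fold changes reached 2.58 upward and -2.39 downward, and the smallest adjusted p in the edgeR test was 0.00719.

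**Figure D2:**
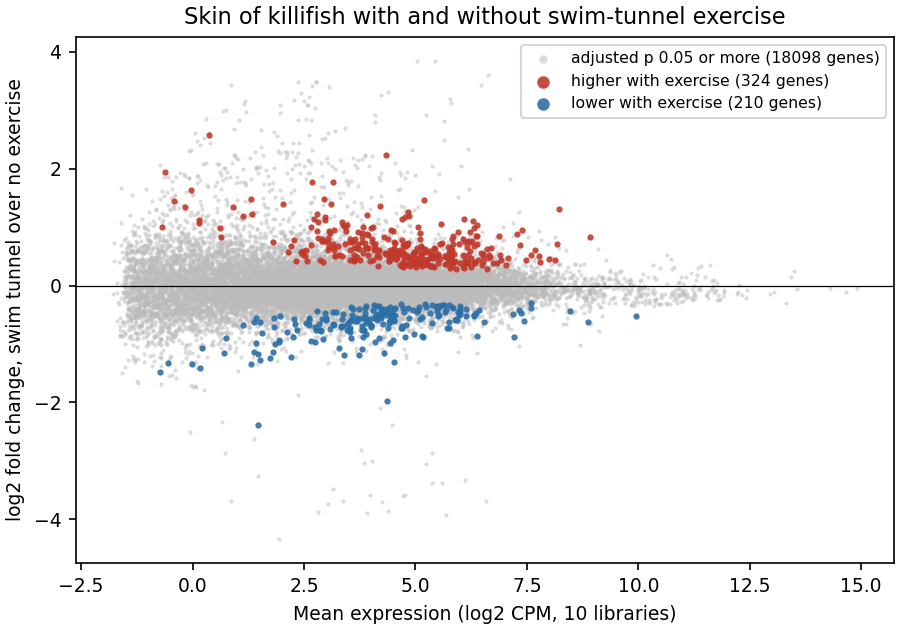
Log2 fold change (exercise over no exercise) against mean log2 CPM for the 18632 tested genes; red and blue points are the 324 higher and 210 lower genes past an adjusted p of 0.05, grey points the others. Changed genes lie mostly within 2-fold of no change, and many grey points with larger fold changes did not pass the test.

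The number of changed genes moved when single libraries were left out, in fits with fewer samples. It was 327, 129, 423, 103 and 590 without exercise-group replicates 1 to 5 in turn. Without replicates 1 to 5 of the group without exercise it was 414, 293, 137, 442 and 207. All 534 genes kept their direction in these 10 fits, which their choice from the same data nearly ensures. In 506 of them the groups did not overlap. In limma on the deposited RPKM values, whose scaling is faulty, 0 genes passed (1326, 1329 and 1098 genes at an unadjusted p under 0.05 in 3 versions). With library totals in place of TMM factors 291 genes passed and 72.5% of them were higher, against 60.7% of the 534. The share was 53.2% of 513 genes with upper quartile factors (273 higher, 240 lower), 52% of 713 with the strict filter and 52.9% of 1583 with DESeq2. At an unadjusted p under 0.05 there were 3611 genes in the edgeR test, where 932 would be expected with no effect. Another split of the same libraries, by sample number, gave 2195 at this level with 0 genes past the adjusted threshold. An excess over 932 thus also arose in a split not made by exercise, so the excess by itself does not point to exercise. It was 1 split, chosen after the data were seen, and does not tell how much of the 3611 has another source.

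The identifiers of the table carry no gene names, so the changed genes are described by their values. Nfu_g_1_008332, with a model of 714 bp, was expressed at 13.6 ± 3.01 CPM with exercise and 3.98 ± 0.797 CPM without (SD, n = 5). This was 3.41-fold higher, at a log2 fold change of 1.77 (standard error 0.19, edgeR adjusted p = 0.00719). Nfu_g_1_010462, of 3691 bp, rose from 4.04 ± 1.14 CPM to 11.3 ± 2.60 CPM, a log2 fold change of 1.48 (standard error 0.25, edgeR adjusted p = 0.0171). Its adjusted p was 0.0528 without exercise-group replicate 2 and 0.0603 without replicate 4 of that group. In the other direction, Nfu_g_1_021184, of 5443 bp, was at 8.28 ± 2.08 CPM with exercise and 32.5 ± 8.71 CPM without. It was 3.93-fold lower, at a log2 fold change of -1.97 (standard error 0.23, edgeR adjusted p = 0.00732). Nfu_g_1_009157, of 4829 bp, was at 1.35 ± 0.533 CPM with exercise and 3.46 ± 1.24 CPM without, a log2 fold change of -1.35 (standard error 0.29, edgeR adjusted p = 0.0375). This gene was no longer past the threshold in 8 of the 10 fits that left out 1 library, and its adjusted p reached 0.105 there (without exercise-group replicate 4). None of the 5 values of one group overlapped those of the other for these 4 genes, a condition of their choice.

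**Figure D3:**
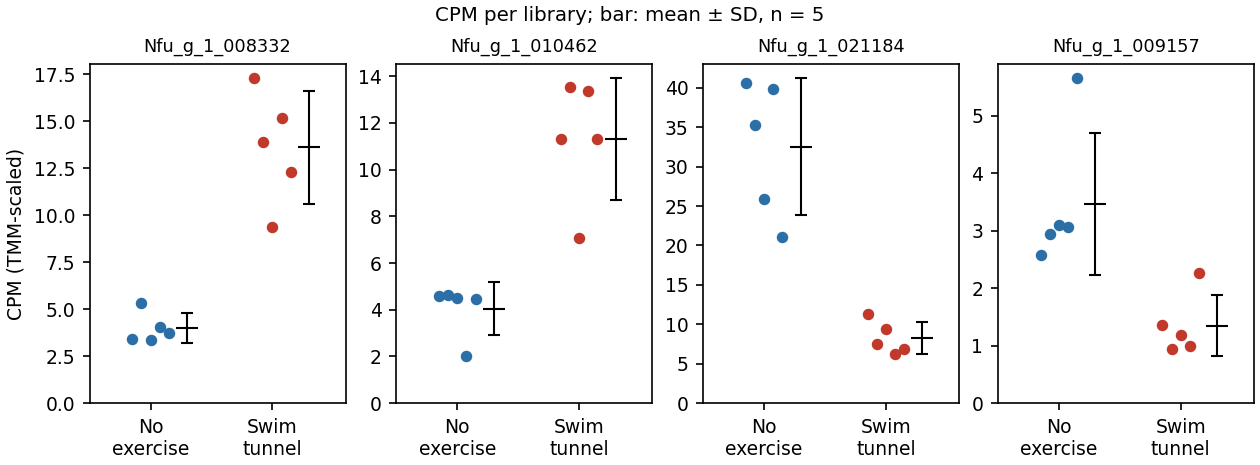
CPM of 4 genes in each library, in blue without and in red with exercise; points are the 5 libraries of a group and bars the mean ± SD. For each gene all values of one group lie above all values of the other.

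The separation of the groups in these genes was shared by most changed genes, which the test selects for at this group size. In 309 of the 324 higher genes every library with exercise lay above every library without, and in 197 of the 210 lower genes every library with exercise lay below. Over all tested genes the groups did not overlap in 1214 (6.52%), where chance gives 0.794%. Changed genes were more abundant than the others, with a median of 27.5 CPM for the higher, 17.6 CPM for the lower and 10.6 CPM for the unchanged genes. Genes with few counts pass the test less readily, so this need not be a trait of the changed genes. In the 5 bands of equal gene number from low to high expression, 11, 21, 73, 108 and 111 genes were higher and 7, 34, 59, 62 and 48 lower. At 100 CPM or more there were 23 higher and 10 lower genes among 1304 tested genes, beside 324 and 210 among all 18632 tested genes.

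The changed genes also differed in length. The median model was 4040 bp long for the higher, 3098 bp for the lower and 2684.5 bp for the unchanged genes. In the 5 bands of equal gene number from short to long, 25, 51, 54, 85 and 109 genes were higher and 38, 40, 37, 55 and 40 lower. Lists of the same size matched on mean expression had median lengths of 2994 to 3684 bp for the higher and 2590 to 3370 bp for the lower genes (95% of 2000 random lists). The higher genes lay above their matched lists and the lower genes within theirs, but this contrast was lost when each library's trend on gene length was removed, a setting chosen after seeing the data. The median was then 3769.5 bp for the higher genes (matched lists 2937 to 3632 bp) and 3767.5 bp for the lower genes (2603 to 3394 bp), both above their matched lists.

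**Figure D4:**
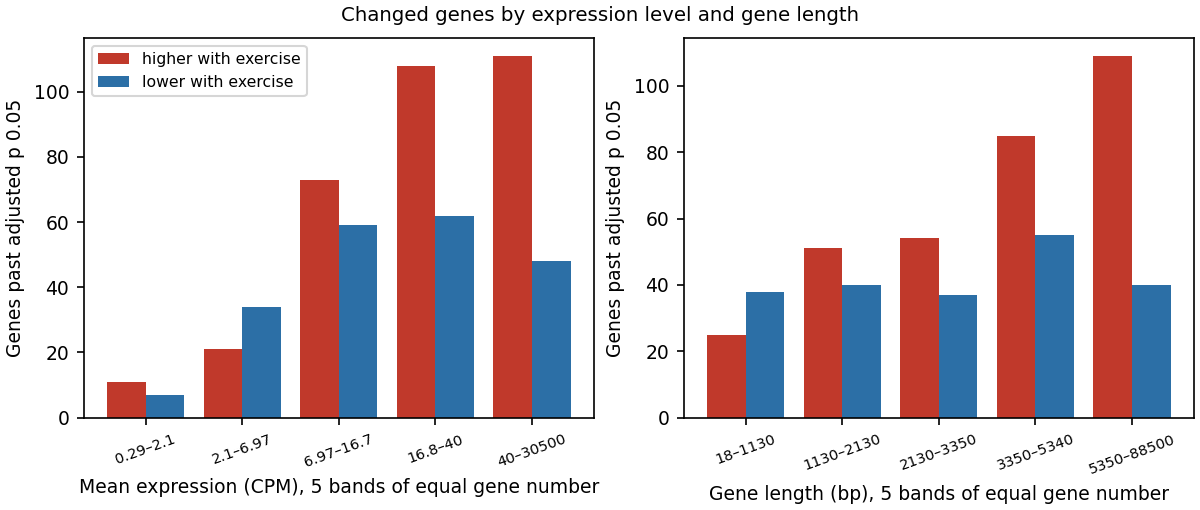
Number of changed genes in 5 bands of equal gene number by mean CPM (left) and by gene length in bp (right), in red higher and in blue lower with exercise. Higher genes go from 11 in the lowest to 111 in the highest expression band and from 25 in the shortest to 109 in the longest.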

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

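The measure of genes seen in a single library was defined after the counts had been examined, and the tests of it were set before their results were known, except the share of genes under 1 CPM and the comparison without both libraries, which were added after. Among 28 groups of 5 values, 9 held a value far from the other 4, where chance gives about 1 in 20, or 1.4. That rate assumes independent values, while several of these measures are related or were chosen from the same data. The 9 are therefore no measured excess over 1.4.

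Exercise-group replicate 1 held 162 genes, and replicate 4 without exercise held 33, that reached at least 1 CPM and over 10 times the level of every other library, against 0 or 1 in the others. They took 9138 CPM (0.914% of counts) and 5343 CPM (0.534%). None of the 92 and 26 of them that were tested was among the changed genes. Their definition nearly ensures this, since 1 library so far above the others widens the spread within its group. Depth is argued against as the whole cause, since 89.51% of the 162 were still seen alone when all libraries were thinned to the smallest total. Exercise cannot be the source of the 33, which were seen in a library without it, and stays open for the 162. Of the 162, 33.33% had a higher mean in the other 4 libraries with exercise than in those without. However, 63.6% had a mean under 1 CPM in the other 9 libraries, too low for this to decide. RNA of another tissue or organism may be the source and stays open too, since 0 identifiers had a name to look up. Without both libraries the count of changed genes was 249 in place of 534.

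The share of counts outside the tested genes was 0.168% in exercise-group replicate 1, against 0.0339 to 0.049% in the other 4. Exercise-group replicate 2 had a total of 22991447 counts, where the others of its group had 33637143 to 36851296. The TMM factor of exercise-group replicate 3 was 1.16, against 0.964 to 1.01 in the others. On the 2nd principal component replicate 4 without exercise scored -54.3, where the others of its group scored 9.4 to 24. On the same component exercise-group replicate 3 scored -51.9, against -4.17 to 14.6. Nfu_g_1_010462 was at 2.01 CPM in replicate 4 without exercise and at 4.46 to 4.64 CPM in the others of its group. Nfu_g_1_009157 was at 5.65 CPM in replicate 5 without exercise and at 2.58 to 3.09 CPM in the others.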

How the results depend on the processing

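The 6 settings named last were chosen after seeing the data; the others were fixed before the data were examined. The count of changed genes stayed within 1.5 times the reported 534 (324 higher, 210 lower) in 12 of 28 settings. It left that range in 16, and unless stated the cause was not tested. At an adjusted p below 0.10 there were 1149 (623 higher, 526 lower), with DESeq2 1583 (838, 745) and with limma voom 1064 (605, 459). With library totals alone there were 291 (211, 80). The strict filter gave 342 lower genes and 1 surrogate variable 126 lower genes. All 3 versions of the deposited RPKM gave 0 changed, 0 higher and 0 lower genes in limma (1326, 1329 and 1098 at an unadjusted p under 0.05), through their mixed-up totals at least in part, since RPKM with own totals gave 261 (188, 73). The 10 fits that left out a library gave 103 to 590 changed, 68 to 315 higher and 35 to 275 lower genes, with fewer samples; the count was 327, 129 and 103 without exercise-group replicates 1, 2 and 4, and 293, 137 and 207 without replicates 2, 3 and 5 of the other group. In all 10, 95 of the 534 genes (64 higher, 31 lower) stayed past the threshold. All 534 kept their direction, which their choice from the same data nearly ensures. In the 27 refits a changed gene took the other sign only with the deposited RPKM, 4 genes in each version. For the 4 named genes 82 values stayed past the threshold, 23 did not and 0 changed sign. These genes were chosen for no overlap between the groups, so their signs could hardly change. The list tests, the list scores and the muscle covariate were not run. Of the added settings, RPKM with own totals is given above; removal of the length trend gave 538 and thinning 533. The 4 against 4 comparison gave 249 (161, 88), with fewer samples, the lower or higher sample numbers as a term 663, and the sample number within its group as a term 970 (548, 422). At this depth and group size 22% of simulated 1.5-fold changes were found, so small changes can be missed.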

Other observations

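The removal of the length trend, all comparisons by sample number and the ratio that weighs exercise against them, and the values on neighbouring genes and gene length were chosen only after the results had been seen.

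Of 100 splits of the libraries into 5 and 5, 2 gave at least the 534 changed genes of the real split, itself included. This share under 0.05 makes a chance division of the libraries unlikely as the source but does not exclude it. The rest of the 126 splits were not drawn. The highest other split gave 599, more than the real one, so the number of calls alone does not set exercise apart from that grouping. The median of the others was 0. For the larger direction 2 splits reached the real 324 (highest other 446), and for the smaller direction 1 reached 210 (highest other 153). The split with 599 set exercise-group replicates 1, 2 and 3 and replicates 1 and 2 without exercise against the other 5, which are the lower and the higher running numbers within each group's titles.

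For the 534 genes that differed with exercise, 2 technical trends are argued against as the whole cause. With each library's trend on gene length removed 93.07% stayed past the threshold, and at equal depth 88.95% did. For a steady drift with the sample number, the shift expected from the slopes within groups would have to match the difference between groups. The median ratio of this shift to that difference was 0.1203 (interquartile range -0.215 to 0.422), with the needed sign in 58.2% of genes. This ratio cannot decide, because slopes within groups add to the spread in the test that chose these genes. A drift with the sample number thus stays open. Separate handling of the groups cannot be told apart from exercise, since 0 samples with exercise (numbers 2 to 6) had a number above any without (8 to 12). An effect of exercise may account for the difference and stays a hypothesis.

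The sample numbers may follow a difference between samples that the labels do not describe. Depth is argued against as its whole cause, since 84.81% of the 599 genes stayed past the threshold at equal depth. In a model with the exercise group as a term, 88.81% of the 599 genes stayed past the threshold (672 calls). A difference between the exercise groups enters the contrast of lower and higher numbers at only 0.2 of its size. Genes chosen for that contrast could thus hardly be lost through the group term, and the 88.81% decides nothing about such a difference. The part that the group difference brings to the contrast of lower and higher numbers had a median of 0.0472 of that contrast (interquartile range 0.0167 to 0.0809), where a sole cause needs about 1. This ratio decides nothing either, because genes chosen for the number contrast could hardly include any with a group difference alone. The 2 libraries with genes seen in them alone stay open: without them the count by number fell from 599 to 78, and without each of the 24 other pairs of 1 lower and 1 higher number it was 7 to 789 (median 155.5), with 78 or fewer in 8 of them. A chance order of the samples stays open too: genes with a slope on the number among samples with exercise had the same sign in those without in 89.8% of 500 genes, a share that 10 of the 120 orders of the samples without exercise reached (highest 94.4). Exercise was tested in other ways before the ratio above was chosen. Beside the model with the group as a term, these were the signs of slopes, which left it undecided, and an overlap of calls. The overlap was 0, against 17.2 for independent lists. It decides nothing either, because each difference adds to the spread in the other comparison.

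What the numbers stand for is not given in the sources used here, and other values by sample number do not settle it. All of the 599 genes (100%) kept their direction without the 2 libraries named above, on data that chose them, so this decides nothing and was replaced by the counts for pairs. With the numbers divided as 2 and 3 instead, edgeR called 0 genes (2195 at an unadjusted p under 0.05). Exercise compared within the lower or within the higher numbers gave 0 calls each (2244 and 2420 at an unadjusted p under 0.05). Each of these fits set 3 libraries of one group against 2 of the other, so few that changes are easily missed. All 534 genes had the same direction in both, on the same data that chose them. With the number within its group as a term, 989 genes had a slope (675 rising, 314 falling), and 113 genes were called for both number and exercise, where independent lists would share 51.5. The terms for the number raised the count of genes that differed with exercise to 663 and 970, and 534 remains the reported value because these terms were found from the same data.

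Adjoining genes that changed in the same direction were more frequent in the count table than in shuffled tables. Among 14242 pairs of tested genes in adjoining rows, 18 changed in the same direction, of which 16 were both higher and 2 both lower. In 10000 shuffles the mean of same-direction pairs was 6.12 and the highest 16 (permutation test, one-sided, p = 1e-04, the smallest these can give). Pairs with opposite directions numbered 5, against a mean of 5.5 in shuffles. The median correlation within groups was 0.095 for adjoining pairs and -0.017 to 0.024 for shuffled pairs. Whether the order of the table follows the genome is not given in the sources used here.

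The values on adjoining genes and on length were first computed as tests of explanations and are given here without one. The spread of log2 CPM was larger with exercise in 50.5% of tested genes, and in 47.5% without exercise-group replicate 1.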
